A study of Mus musculus with 42 samples.

How the data were processed

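Bulk RNA of sorted Treg and Tconv from the ileum, the mesenteric node, the ankle synovium and the joint nodes of TNFdARE and WT mice was profiled in 42 libraries. Per the submitters' protocol, RNA entered a SMART-Seq v4 full-length cDNA protocol at 1 of 2 stated input amounts, and which library had which amount is not stated. The deposited count table holds raw counts of 46603 Ensembl genes, unnormalised. The FPKM values in the second table were made by the authors, and any normalisation between samples is not stated. That table holds 18964 of the genes, no value in it is 0, and 97.2% of its genes hold a value repeated exactly in 2 or more libraries. Per the submitters' processing notes, cutadapt 1.15 and Bowtie2 2.3.3.1 were used with the GRCm38 build. The alignment settings, the counting program and the annotation release are not stated. Symbols and positions came from the GENCODE M21 annotation, which gave a symbol to 46005 of the identifiers and none to 598.

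Tests ran on the counts. The FPKM values served only as a check: with a pseudocount of 1, differences of mean log2 FPKM were compared across genes with the fitted log2 fold changes of the 8 genotype comparisons (Pearson's r between 0.718 and 0.957, over genes, which are not independent replicates). Called genes had the same sign in both, except 2 of 717 in Treg of the joint nodes. Groups follow the labels for cell type, site and genotype, and replicates are named by the experiment letter in the titles. Total counts lay between 18261064 and 30301202 per library. With PCR reads and no molecular identifiers, floors cover counting error only.

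Each site was fitted on its own with edgeR 4.0.16 (R 4.3.3), with 1 mean per group of cell type and genotype, TMM normalisation, the filterByExpr filter and the quasi-likelihood F test. Comparisons between sites used the Treg libraries of both sites. Adjusted p-values are Benjamini-Hochberg values over all genes tested in a comparison, and a gene passed when its value was below 0.05. Comparisons were TNFdARE against WT in each cell type and site, Treg against Tconv at each site, tissue Treg against Treg of the draining node, and 3 interactions. Treg against Tconv and tissue against node averaged over both genotypes. Fold changes against a group with no count used a floor of 3 counts over the group. CPM values of single genes used the TMM library sizes, while CPM summed over a list and the plot of Foxp3 used total counts alone. Log2 CPM had a prior count of 2.

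A fixed set of 27 gene lists (308 genes, all found in the table) was tested with camera of limma 3.58.1 at a preset correlation of 0.01, adjusted over the lists of a comparison with at least 3 tested genes. Camera compares a list with the other genes. As alternatives, camera ran with an estimated correlation, on ranks and with a replicate block, and fry tested whether the genes of a list move on balance one way, without comparing them with other genes. Of 197 list results past the test with the preset correlation, 34 held with the estimated one, and the report gives that value beside each list described that passed. Counts of list genes are given over all genes tested and adjusted over the list alone.

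The comparisons, the tests, the lists and the rule for naming genes were fixed before the data were examined. The rule named Tnf and Foxp3 in every comparison. It added up to 8 rising and 8 falling genes with the largest fitted change among those that passed, had a mean log2 CPM of at least 3 and did not overlap between the libraries of the compared sides (the last condition was dropped for interactions). Predicted genes, pseudogenes, antigen receptor segment genes and sex-linked genes were left out of this part. It also added up to 4 members of each list with the smallest adjusted p among those past the test. Other members of a described list may be named with their values. The tally of Ttn over the 8 genotype comparisons and the genes beside Tnf on chromosome 17 were singled out after their values were seen. Some genes that the rule named are not reported here.

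Experiment letters were not used as pairs in the main test. As a check, deviations from the group means were correlated between TNFdARE and WT libraries of the same letter, over genes. Of 18 such pairs 13 had r above 0.1 (0.03 to 0.5, median 0.29), and the letter as an additive replicate block was run as an alternative. Further alternatives were a fit of only the 2 groups compared or of all 42 libraries, DESeq2 1.42.0 with its own size factors, RLE factors, no filter beyond 1 count, limma voom with sample quality weights, and the omission of each library in turn. A sample-sheet pass (sheet numbers 1 to 32 against 33 to 44) served as a covariate where it could be estimated. A pair of alternatives was added after the data were seen: omission of the libraries with the most genes detected, and of the experiment A ileal Treg libraries with the most plasma cell RNA. Totals, genes detected, the share of the 100 most abundant genes, the mitochondrial share and marker CPM were compared between genotypes by exact two-sided permutation tests where both groups held 3 libraries. The smallest p of such a design is 0.1, and its adjusted value was 0.367, so these tests cannot show a difference.

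The functions were tested on simulated data drawn from the dispersions that edgeR fitted at each site, with changes placed in TNFdARE Treg. All groups of a site had the same simulated spread, whereas real ileal Treg varied more between replicates than ileal Tconv. The rates below may therefore be too favourable for ileal Treg, and the dispersions may favour edgeR over DESeq2. In Treg of the joint nodes the edgeR fit recovered 62.7% of genes changed 1.5-fold and 98.5% of those changed 2-fold, with 13 false calls among 187. In mesenteric Treg it recovered 50.7% and 92.5%, with 11 false calls among 172. In ileal Treg it recovered 6% and 46.3%, and 78.8% of those changed 4-fold, with 5 false calls among 92. In synovial Treg it recovered none changed 2-fold and 30.3% of those changed 4-fold, with 2 false calls among 22. On the same simulated sets DESeq2 made 38 false calls among 219, 36 among 216, 76 among 195 and 176 among 228.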

Results

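Regulatory T cells (Treg) and conventional CD4 T cells (Tconv) were sorted by a green fluorescent reporter of Foxp3 from 4 sites of mice: the ileum, the mesenteric lymph node that drains it, the ankle synovium, and the inguinal and popliteal nodes that drain the ankle (here the joint nodes). TNFdARE mice, in which the Tnf transcript lacks a destabilising AU-rich element, were compared with wild-type (WT) littermates. Bulk RNA sequencing gave 42 libraries in 16 groups of cell type, site and genotype, from 3 experiments named A, B and C. Each group held 3 libraries, except TNFdARE mesenteric Treg and Tconv (2 each, B and C), TNFdARE synovial Tconv and WT synovial Treg (2 each, A and B) and WT synovial Tconv (1, A), which has no replicate. Each library held between 18261064 and 30301202 counts. Values after log2 fold changes are standard errors from the fit, and those after CPM (counts scaled to a common library size) are standard deviations between libraries. Nothing in the labels says how many animals a library comes from, and both Xist and Ddx3y transcripts were found in every library, so p-values measure the spread between samples. That spread was pooled over all groups of a fit, so within a site Treg and Tconv share it. Floors and counting intervals cover counting error only.

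The comparison of Treg with Tconv shows what the reporter sort separated at each site, with both genotypes weighted equally. In the nodes, Treg carried the regulatory program far above Tconv. Foxp3 (ENSMUSG00000039521, chromosome X, 7573644 to 7595245 in GRCm38), the transcription factor that defines the lineage, was 77.0-fold higher in mesenteric Treg (log2 fold change 6.27 ± 0.15, adjusted p = 2e-10, 5 libraries against 5). It was 74.7-fold higher in Treg of the joint nodes (6.22 ± 0.09, adjusted p = 1.6e-15, 6 against 6). Il2ra, the high-affinity interleukin-2 receptor chain, was 52.0-fold and 77.1-fold higher, and Lrrc32, which anchors latent TGF-beta on Treg, 256-fold and 189-fold higher. All 15 genes of the Treg core list were higher at both node sites (15 adjusted over the list alone at each; camera adjusted p = 7e-16 and 2.9e-18, or 0.064 and 0.032 with an estimated correlation). All 19 effector and tissue Treg genes were higher at both as well (19 adjusted over the list alone; camera adjusted p = 2.7e-12 and 4.2e-15, or 0.16 and 0.032 with an estimated correlation). Genes of naive cells and node retention moved the other way, with 13 of 13 lower in mesenteric Treg and 10 of 13 in the joint nodes (13 and 10 adjusted over the list alone; camera adjusted p = 3.9e-10 and 3.4e-08, or 0.064 and 0.06 with an estimated correlation). Dapl1 fell by 4.39 on the log2 scale in mesenteric Treg and fell by 4.43 in the joint nodes, relative to Tconv. Proliferation genes were higher in Treg of the joint nodes, where 14 of 18 passed the test (15 adjusted over the list alone; camera adjusted p = 9.1e-07, or 0.13 with an estimated correlation), with Mki67, a marker of cycling cells, 6.95-fold higher. Tnf (ENSMUSG00000024401, chromosome 17, 35199381 to 35202007) was 1.71-fold higher in Treg of the joint nodes (0.78 ± 0.18, adjusted p = 0.0023). In the mesenteric node Tnf was 1.49-fold higher (0.58 ± 0.20, adjusted p = 0.041), a call lost without Treg WT A or B or TNFdARE B, or Tconv WT B or C or TNFdARE B or C (adjusted p from 0.063 to 0.26). Across all genes, 5720 of 14820 passed in the mesenteric node and 6351 of 14691 in the joint nodes. A single fit of all 42 libraries called 2437 and 2980.

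Ileal Treg and Tconv were separated by the regulatory genes on one side and by effector cytokines on the other. Foxp3 was 27.6-fold higher in ileal Treg (4.79 ± 0.16, adjusted p = 5e-08, 6 against 6), and Il10, an anti-inflammatory cytokine, 10.1-fold higher (3.33 ± 0.18). Il17a, the signature cytokine of type 17 cells, was 47.5-fold lower in Treg (-5.57 ± 0.23, adjusted p = 1.7e-07), Il22, which acts on epithelium, 38.6-fold lower, and Ifng, the type 1 cytokine, 26.8-fold lower. Ileal Tconv held Il17a at 1229 ± 419 CPM in TNFdARE and 626 ± 184 CPM in WT, against 18.9 ± 5.77 and 17.9 ± 1.32 CPM in Treg (n = 3 each). All 15 Treg core genes were higher in Treg (15 adjusted over the list alone; camera adjusted p = 3.2e-24, or 0.0037 with an estimated correlation). Of 13 type 17 genes, 8 were lower and 5 did not pass (8 adjusted over the list alone; camera adjusted p = 6.3e-06, or 0.03 with an estimated correlation). Of 18 type 1 and cytotoxic genes, 10 were lower and 1 higher (11 and 1 adjusted over the list alone; camera adjusted p = 2.7e-06, or 0.08 with an estimated correlation). The CD8 and NK marker list moved the same way, with 4 of 5 genes lower (4 adjusted over the list alone; camera adjusted p = 0.0014, or 0.048 with an estimated correlation), so cytotoxic transcripts of Tconv were not separated from RNA of such cells. Tnf itself was 2.89-fold lower in ileal Treg (-1.53 ± 0.13, adjusted p = 1.8e-05). Markers of other cells differed both ways. Of 9 B cell genes 3 were higher in Treg and 2 lower (5 and 3 adjusted over the list alone; camera adjusted p = 0.3). The epithelial gene Epcam was 9.8-fold higher than in Tconv, and Igha, the antibody heavy chain of plasma cells, 10.5-fold higher (3.39 ± 0.87), a call lost without Treg WT A or Tconv WT A, B or C or TNFdARE B or C (adjusted p from 0.055 to 0.071). Igha varied widely between Treg libraries, at 1669 ± 2551 CPM in TNFdARE and 753 ± 672 CPM in WT. In TNFdARE Treg the plasma cell list summed to 5677 CPM in experiment A, 398.1 in B and 122.5 in C. In all, 2353 of 15916 genes passed, a number that was 1541 without the WT Tconv library of experiment C and 1264 with the sample-sheet pass as a covariate.

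**Figure D1:**
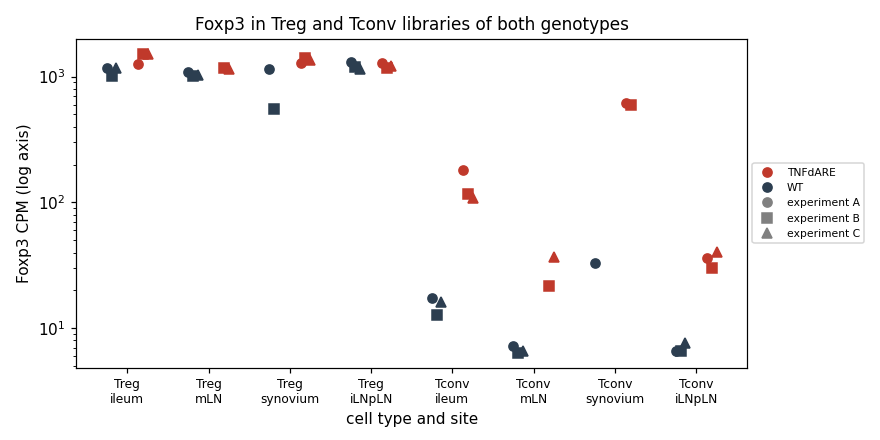
Foxp3 in CPM on a log axis, 1 point per library, for Treg and Tconv of each site and genotype. Scaled by total counts alone, TNFdARE synovial Tconv stand at 604 CPM on average and WT synovial Tconv at 32.9 CPM. The group means of Treg lie between 856 and 1422 CPM. WT synovial Treg B, at 556 CPM, lies below TNFdARE synovial Tconv A and B (611 and 596 CPM).

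The synovial comparison rests on a single WT Tconv library. Foxp3 was 7.74-fold higher in synovial Treg (2.95 ± 0.28, adjusted p = 0.0068, 5 libraries against 3). TNFdARE Tconv themselves held 617 ± 2.15 CPM of Foxp3 (n = 2), against 31.1 CPM in the WT library, while Treg held 1411 ± 58.4 and 869.2 ± 428.4 CPM. Ctla4, an inhibitory receptor of Treg, was 4.03-fold higher in Treg, Klrg1, a marker of terminally differentiated Treg, 5.3-fold, Il10 7.08-fold, and Il1rl1, the interleukin-33 receptor, 5.07-fold. Areg, a growth factor of tissue repair, was 6.07-fold higher. Of the 15 Treg core genes, 9 were higher and 6 did not pass (14 adjusted over the list alone; camera adjusted p = 2.8e-16, or 0.054 with an estimated correlation). The co-inhibitory receptor list had 3 of 12 genes higher (7 higher and 3 lower adjusted over the list alone; camera adjusted p = 0.041, upward, or 0.22 with an estimated correlation), although its median log2 fold change was 0.94 and its mean -0.35. Markers of other cells differed too: Dcn, made by fibroblasts, was 11.7-fold higher in Treg, and Cd8a stood at 254.8 CPM in the WT Tconv library and 14.5 ± 11.8 CPM in TNFdARE Tconv. In all 197 of 17959 genes passed. Without TNFdARE Tconv A or B the number was 45 or 62, without TNFdARE Treg A or B 103 or 126, and without WT Treg B 1287. It was 71 with a replicate block, 41 by voom, 106 with the sample-sheet pass, 391 without a filter, 1601 by DESeq2 and 3262 in a fit of all 42 libraries.

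The next comparisons ask how TNFdARE cells differ from WT within each population and site. In ileal Treg (n = 3 and 3), Ccr6, Stab1 and Slc15a3 were higher in TNFdARE and Gpr83 was lower. Ccr6, a chemokine receptor of mucosal T cells, was 3.9-fold higher (1.96 ± 0.13, adjusted p = 0.00012), at 240.7 ± 20.6 CPM against 60.6 ± 2.20. Stab1, a scavenger receptor, was 3.74-fold higher (1.90 ± 0.15, adjusted p = 0.00041) and Slc15a3, a lysosomal peptide transporter, 4.2-fold higher. Itgae, the integrin chain that binds epithelial E-cadherin, was 2.35-fold higher (1.23 ± 0.24, adjusted p = 0.043). Gpr83, a receptor of resting Treg, was 3.24-fold lower (-1.70 ± 0.17, adjusted p = 0.0019). Of the 13 type 17 genes, 2 were higher and 11 did not pass (7 higher adjusted over the list alone; camera adjusted p = 6.7e-05, or 0.069 with an estimated correlation). Naive and retention genes included 2 lower among 13, Lef1 and Tcf7 (1 higher and 7 lower adjusted over the list alone; camera adjusted p = 0.001, or 0.52 with an estimated correlation). The interferon list as a whole did not pass (2 higher and 1 lower of 22; 5 and 4 adjusted over the list alone; camera adjusted p = 0.52), with a median log2 fold change of 0.22 and a mean of -0.14. Tnf was at 39.2 ± 4.42 CPM against 23.1 ± 4.76 and did not pass (adjusted p = 0.1), nor did Foxp3 (0.41 ± 0.20, adjusted p = 0.42).

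In total 116 of 15916 genes passed in ileal Treg, 77 of them higher. The number was 36 without TNFdARE B, 53 without WT A and 695 without WT B, and it was 5 with only these 2 groups in the fit, 25 by voom, 238 with a replicate block and 722 by DESeq2. Over genes, log2 CPM of replicates correlated at 0.901 to 0.970 in ileal Treg and at 0.980 to 0.988 in ileal Tconv. The main fit pools the spread of these cell types. Of the 21 named calls, 7 passed in every fit that left out a single library, among them Ccr6, Stab1, Slc15a3 and Gpr83. Itgae did not pass without any 1 library but WT B (adjusted p from 0.072 to 0.15), nor did Lef1 and Tcf7 without TNFdARE A or B or WT A or C (0.084 to 0.15 and 0.068 to 0.2). The libraries of experiment A held the most plasma cell RNA (5677 CPM summed over the plasma cell list in TNFdARE and 2035.5 CPM in WT).

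In mesenteric Treg (n = 2 TNFdARE and 3 WT), Stab1, Il1r2, Ccr9, Gpr15 and Ccr2 were higher in TNFdARE, and interferon-induced genes were lower. Stab1 was 18.1-fold higher (4.18 ± 0.23, adjusted p = 9e-06), and Il1r2, a decoy receptor of interleukin-1, 7.4-fold higher (2.89 ± 0.22, adjusted p = 6.3e-05). Among receptors that guide cells to tissue, Ccr9, the small-intestine homing receptor, was 4.13-fold higher (2.05 ± 0.22), Gpr15, the colon homing receptor, 4.0-fold (2.00 ± 0.23) and Ccr2, a receptor for inflammatory chemokines, 4.5-fold (2.17 ± 0.23). Itgae was 3.72-fold higher (1.90 ± 0.19, adjusted p = 0.00022), Gzmb, a cytotoxic protease, 9.08-fold (3.18 ± 0.33) and Cd74, the MHC class II invariant chain, 5.54-fold (2.47 ± 0.16, adjusted p = 2.4e-05). The TNFdARE libraries differed widely in Gzmb, at 124.2 ± 59.1 CPM against 14.2 ± 3.27 in WT. The type 17 list had 10 of 13 genes higher (11 adjusted over the list alone; camera adjusted p = 1.4e-09, or 0.28 with an estimated correlation), among them Ccr6 and Ltb4r1. The TNF and NF-kB list had 7 of 18 genes higher (11 higher and 2 lower adjusted over the list alone; camera adjusted p = 3.6e-05, or 0.35 with an estimated correlation), including Nfkb2 and Relb of the non-canonical pathway, 1.9-fold and 1.89-fold higher, and Tnf (2.25-fold, 1.17 ± 0.28, adjusted p = 0.031). The Tnf call was lost without WT A, B or C (adjusted p = 0.063, 0.068 and 0.087) or TNFdARE B (adjusted p = 0.38).

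Interferon-induced genes were lower in the same mesenteric Treg. Of 22 list genes, 13 were lower and 1 higher (14 and 1 adjusted over the list alone; camera adjusted p = 2.6e-08, or 0.35 with an estimated correlation). Ifit3, an antiviral protein, was 16.7-fold lower (-4.06 ± 0.54, adjusted p = 0.0011), at 6.65 ± 2.76 CPM against 114.3 ± 50.4, and Usp18, which restrains interferon signalling and is induced by it, 5.33-fold lower (-2.41 ± 0.32, adjusted p = 0.0011). Of 13 naive and retention genes, 8 were lower, such as Lef1 and Satb1, and 1 was higher, Il7r, the interleukin-7 receptor (1 higher and 10 lower adjusted over the list alone; camera adjusted p = 2.4e-05, or 0.28 with an estimated correlation). The B cell list held 2 higher genes of 7 (4 adjusted over the list alone; camera adjusted p = 0.02, or 0.35 with an estimated correlation), and Ighm was 1.77-fold higher (0.83 ± 0.11). Foxp3 did not pass (0.21 ± 0.16, adjusted p = 0.52). In total 842 of 14820 genes passed, 569 of them higher. The number was 221 without TNFdARE B, 400 without WT B, 1343 by DESeq2 and 1405 without a filter.

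In Treg of the joint nodes (n = 3 and 3), 838 of 14691 genes passed, 494 of them higher. Penk, the precursor of enkephalin peptides, was 7.63-fold higher in TNFdARE (2.93 ± 0.22, adjusted p = 3.3e-06), Il1r2 6.87-fold (2.78 ± 0.18, adjusted p = 1.2e-06), Gpr15 5.74-fold (2.52 ± 0.16, adjusted p = 6.4e-07) and Ccr6 3.46-fold (1.79 ± 0.12, adjusted p = 1.4e-06). Vcam1, an adhesion molecule, stood at 30.7 ± 6.06 CPM against 0.723 ± 0.431, and Itgae was 2.64-fold higher (1.40 ± 0.20). Il2ra was 1.32-fold lower (-0.40 ± 0.08, adjusted p = 0.011), a call lost without TNFdARE A (adjusted p = 0.073) or WT A (adjusted p = 0.055). Interferon-induced genes were again lower: 16 of 22 fell and none rose (17 adjusted over the list alone; camera adjusted p = 3.6e-18, or 0.052 with an estimated correlation), with Ifit3 8.05-fold lower (-3.01 ± 0.28) and Usp18 3.11-fold lower (-1.64 ± 0.12, adjusted p = 3.8e-06). The TNF and NF-kB list had 7 genes higher and 1 lower of 18 (7 and 1 adjusted over the list alone; camera adjusted p = 0.0078, or 0.26 with an estimated correlation), with Nfkb2 1.69-fold and Tnfrsf1b, the TNF receptor enriched on Treg, 1.42-fold higher. Of the Treg core list 5 genes were higher, such as Nrp1 at 1.87-fold, and 1 lower (7 and 3 adjusted over the list alone; camera adjusted p = 0.053). The B cell list had 3 of 8 genes higher (4 adjusted over the list alone; camera adjusted p = 0.0027, or 0.052 with an estimated correlation), among them Igkc at 2.52 ± 0.24 and Ighm at 0.53 ± 0.07 on the log2 scale. Foxp3 did not differ detectably (0.00 ± 0.10), nor did Tnf (0.41 ± 0.25, adjusted p = 0.39). The number of genes was 332, 499 and 446 without TNFdARE A, B or C, 342 and 463 without WT B or C, 506 with the sample-sheet pass, 1503 by DESeq2, 1524 with a replicate block and 1726 by voom.

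Synovial Treg (n = 3 TNFdARE and 2 WT) gave 28 genes of 17959, 20 of them higher. Pcsk1, a prohormone protease, was 11.7-fold higher in TNFdARE (3.55 ± 0.24, adjusted p = 0.014), Pdcd1, the inhibitory receptor PD-1, 5.78-fold (2.53 ± 0.27, adjusted p = 0.034) and Klrg1 3.29-fold (1.72 ± 0.20, adjusted p = 0.043). Npnt, an extracellular matrix protein, was 15.5-fold higher. Ccdc184 had no count in either WT library and stood 877-fold above a floor of 3 counts over the group. That floor covers counting error only and is no bound if transcripts were lost before sequencing. The WT libraries A and B detected 13341 and 16324 genes, against 15547, 20171 and 15638 in TNFdARE A, B and C. Over genes, log2 CPM correlated at 0.836 between the WT libraries and at 0.914 to 0.938 between those of TNFdARE. Bcl2, a survival factor, was 5.12-fold lower (-2.36 ± 0.29, adjusted p = 0.048), and Gpx3 and Dcn, secreted by stromal cells, were 16.9-fold and 7.42-fold lower. The summed CPM of the fibroblast and stroma list was 5387 ± 3325 in TNFdARE against 19374 ± 741 in WT. Effector and tissue Treg genes had 3 of 19 higher (11 adjusted over the list alone; camera adjusted p = 7.9e-07, or 0.43 with an estimated correlation). No interferon gene passed (0 of 22, and 0 adjusted over the list alone), with a list median of -0.75 (camera adjusted p = 0.00014, or 0.43 with an estimated correlation). None of the named calls passed in every fit that left out a library, as Klrg1, Pdcd1 and Bcl2 were lost without WT A or any TNFdARE library, and Pcsk1 and Gpx3 without WT A or TNFdARE B or C. The number of genes was 6 without TNFdARE A, 0 without TNFdARE B, TNFdARE C or WT A (edgeR, with 1455, 1285 and 1612 at an unadjusted p under 0.05), and 1419 without WT B. It was 0 with a replicate block (edgeR, 1052 unadjusted), 1 by voom, with the sample-sheet pass or with these 2 groups alone, 140 without a filter and 924 by DESeq2.

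**Figure D2:**
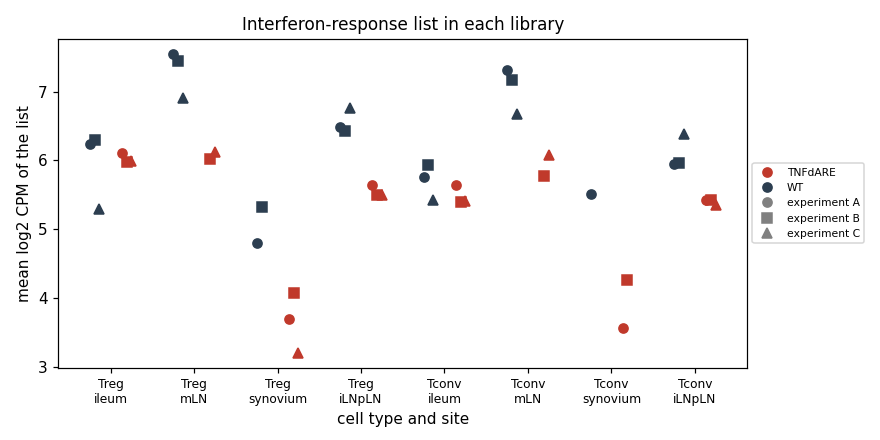
Mean log2 CPM of the 22 interferon-response genes, 1 point per library, by cell type, site and genotype. In both node sites the TNFdARE libraries lie below the WT libraries of the same cell type, while in the ileum they overlap. In the synovium TNFdARE minus WT of the same experiment was -1.11 and -1.26 in Treg (A and B) and -1.95 in Tconv (A, the only WT library).

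Among Tconv, Foxp3 and other genes of the Treg program were higher in TNFdARE at every site. The synovium rests on 1 WT library, and its Foxp3 call was lost with the replicate block. In ileal Tconv (n = 3 and 3), Foxp3 was 9.08-fold higher in TNFdARE (3.18 ± 0.22, adjusted p = 6e-05), at 146.3 ± 46.6 CPM against 16.2 ± 2.62, still below the 1554 ± 137 CPM of TNFdARE ileal Treg. Ikzf4, a zinc finger partner of Foxp3, was 5.36-fold higher (2.42 ± 0.16, adjusted p = 4.5e-05), Klrg1 14.4-fold (3.85 ± 0.45), Havcr2, the inhibitory receptor TIM-3, 8.8-fold (3.14 ± 0.27) and Areg 4.18-fold (2.06 ± 0.22). Of 15 Treg core genes 8 were higher and 1, Gpr83, lower (12 and 2 adjusted over the list alone; camera adjusted p = 1.6e-17, or 0.004 with an estimated correlation). Chemokine receptors of inflamed tissue had 4 of 10 higher (7 adjusted over the list alone; camera adjusted p = 1.8e-12, or 0.0036 with an estimated correlation), such as Ccr1 at 6.12-fold and Ccr8 at 4.67-fold. The neutrophil list, of cells that also carry Ccr1, summed to 57.0 ± 41.6 CPM in TNFdARE against 8.1 ± 1.02 CPM in WT. Its member Mmp9 alone stood at 60.5 ± 44.3 against 8.31 ± 0.922 CPM with TMM library sizes. The sum was thus almost all Mmp9, and the other list genes gave no sign of neutrophil RNA. Type 17 genes had 2 of 13 higher (6 adjusted over the list alone; camera adjusted p = 9.1e-11, or 0.0036 with an estimated correlation). Lef1, of the naive list, was 2.07-fold lower (-1.05 ± 0.13). In the interferon list 3 genes were higher, such as Gbp3, and 3 lower, such as Usp18 and Rtp4 (6 and 5 adjusted over the list alone; camera adjusted p = 0.9; median -0.11 and mean -0.24, while camera's statistic was upward). Usp18 was lost without any library but TNFdARE B (adjusted p from 0.056 to 0.079) and Rtp4 without any but WT C (0.065 to 0.092). Tnf did not pass (0.09 ± 0.17, adjusted p = 1). In all 208 of 15916 genes passed, 186 of them higher. The number was 105 without WT A or TNFdARE B, 107 without WT B, 117 without TNFdARE C, 92 without WT C, 338 with a replicate block, 559 by DESeq2, 636 with these 2 groups alone and 1024 by voom.

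Mesenteric Tconv (n = 2 TNFdARE and 3 WT) had Foxp3 4.3-fold higher (2.10 ± 0.17, adjusted p = 6.3e-05), Itgae 4.96-fold (2.31 ± 0.21, adjusted p = 0.00012) and Il1r2 13.2-fold (3.73 ± 0.28, adjusted p = 4.4e-05). Of 15 Treg core genes 14 were higher (15 adjusted over the list alone; camera adjusted p = 1.4e-21, or 0.051 with an estimated correlation). The type 17 list had 8 of 13 higher (12 adjusted over the list alone; camera adjusted p = 1.6e-15, or 0.11 with an estimated correlation). Follicular helper genes had 4 of 11 higher (8 adjusted over the list alone; camera adjusted p = 1.6e-07, or 0.16 with an estimated correlation), with Cxcr5, the follicle homing receptor, 2.39-fold higher. Interferon genes had 11 of 22 lower and 1 higher (16 and 3 adjusted over the list alone; camera adjusted p = 5.3e-12, or 0.19 with an estimated correlation), with Ifit3 13.5-fold lower and Rsad2, an antiviral enzyme, at -3.81 ± 0.55 on the log2 scale. Tnf was 2.13-fold higher without passing (1.09 ± 0.28, adjusted p = 0.076). In total 350 of 14820 genes passed, 265 of them higher, against 131 without TNFdARE C, 209 without WT A, 218 without WT B, 680 by DESeq2 and 884 without a filter. Of the 24 named calls 18 passed in every fit leaving out a library, and Cxcr5 was lost without WT A or B (adjusted p = 0.11) or TNFdARE C (adjusted p = 0.37).

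In Tconv of the joint nodes (n = 3 and 3), Nrp1, a surface marker of Treg from the thymus, was 4.32-fold higher (2.11 ± 0.08, adjusted p = 2.4e-09), Foxp3 5.19-fold (2.37 ± 0.11, adjusted p = 2.5e-08) and Il1r2 37.4-fold (5.23 ± 0.28). Foxp3 stood at 34.8 ± 4.34 CPM against 6.79 ± 0.814. Of 15 Treg core genes 14 were higher (15 adjusted over the list alone; camera adjusted p = 2e-34, or 0.006 with an estimated correlation), and of 19 effector and tissue Treg genes 11 (14 adjusted over the list alone; camera adjusted p = 7.7e-19, or 0.015 with an estimated correlation). The TNF and NF-kB list had 9 of 18 higher (11 higher and 1 lower adjusted over the list alone; camera adjusted p = 1.5e-10, or 0.015 with an estimated correlation), with Nfkb2 2.08-fold and Relb 1.95-fold higher, while Tnf did not pass (0.57 ± 0.25, adjusted p = 0.41). Interferon genes had 12 of 22 lower and 2 higher (15 and 3 adjusted over the list alone; camera adjusted p = 2.3e-13, or 0.034 with an estimated correlation), with Ifit3 5.71-fold and Usp18 2.2-fold lower. Igkc, an antibody light chain, stood at 2.92 ± 0.392 CPM against 0.0571 ± 0.0498. In total 410 of 14691 genes passed, 336 of them higher, and 242 with these 2 groups alone. The TNFdARE B and WT C libraries had the most genes detected of all, 29599 and 31454, and without both the number was 413.

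In synovial Tconv (n = 2 TNFdARE and 1 WT) the lone WT library is assumed to vary like the other groups of the fit, so the p-values hold no spread of its own. Under that assumption Foxp3 was 20.2-fold higher in TNFdARE (4.34 ± 0.48, adjusted p = 0.014), Tnfrsf9, the costimulatory receptor 4-1BB, 62.5-fold (5.97 ± 0.52, adjusted p = 0.0058), Il10 30.1-fold (4.91 ± 0.45) and Ctla4 5.22-fold (2.38 ± 0.24). The Foxp3 call was lost without TNFdARE A (adjusted p = 0.069) or B (adjusted p = 0.073), and with the replicate block (adjusted p = 0.11), while that of Ctla4 was lost without B (adjusted p = 0.067). Lrrc32 had no count in the WT library and stood 254-fold above the floor, and Pparg, a nuclear receptor of tissue Treg, 534-fold. The floor covers counting error only and is no bound if transcripts were lost before sequencing. The WT library detected 15452 genes, against 16054 and 20097 in TNFdARE A and B. Of 15 Treg core genes 8 were higher (14 adjusted over the list alone; camera adjusted p = 3e-13, or 0.046 with an estimated correlation). Ccl5, a chemokine of cytotoxic cells, was 13.6-fold lower (-3.76 ± 0.28, adjusted p = 0.004), and the summed CPM of the CD8 and NK list was 275 ± 26.2 in TNFdARE against 1640 in WT. Fibroblast and stroma genes summed to 2094 ± 948 CPM against 762. In total 92 of 17959 genes passed, 90 of them higher. Without TNFdARE A or B the number was 26 or 28, and it was 2 with a replicate block, which ended 18 of the 19 named calls. Other settings gave 36 with the sample-sheet pass, 45 by voom, 231 without a filter, 884 with these 2 groups alone and 1186 by DESeq2.

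Genotype effects overlapped between sites. No library was shared between the comparisons set side by side, but their libraries came from the same experiments, and Treg and Tconv of a site shared a fit. The numbers by chance below assume independent comparisons, so the excess was not separated from these shared sources. Ttn, which encodes the giant muscle protein titin (ENSMUSG00000051747, chromosome 2, 76703980 to 76982547), was higher in TNFdARE in 8 of the 8 genotype comparisons. Its call was lost in ileal Treg without WT A or C or TNFdARE B or C (adjusted p from 0.054 to 0.087), in synovial Treg without WT A or any TNFdARE library (0.072 to 0.098), and in Tconv of the joint nodes without WT A or B or TNFdARE C (0.07 to 0.11). Both synovial calls, of which that of Tconv rests on 1 WT library, were lost with the replicate block (adjusted p = 0.23 in Treg and 0.071 in Tconv). In ileal Tconv the call of Itgae was lost without WT B or C (adjusted p = 0.054 and 0.055), and its losses in ileal Treg are given with that comparison. Itgae and Penk were higher in 7, and 21 further genes in 6, including Ccr6, Ccr8, Cd74, Klrg1, Ikzf4 and Tnfrsf4. Usp18 and Ifi214, both interferon-induced, were lower in 6. Of the genes higher in mesenteric Treg and in Treg of the joint nodes, 219 were shared (18.8 by chance), and of those lower 122 (6.6 by chance). Mesenteric and joint-node Tconv shared 157 higher genes (6.1 by chance). In the ileum Treg and Tconv shared 49 higher genes (0.9 by chance). In the synovium, whose Tconv rest on 1 WT library, the replicate block ended all 17 named calls of Treg, so overlaps with synovial lists depend on leaving it out. Ileal and synovial Treg shared 3 (0.1 by chance) of the 77 and 20 called. Of those 20, 17 were also higher in synovial Tconv (0.1 by chance), and 11 of the 18 tested in both were higher in mesenteric Treg (0.7 by chance).

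Interactions tested whether a genotype effect itself differed. Between cell types of the joint nodes, 66 of 14691 genes differed, in 56 of them with a more negative log2 change in Treg than in Tconv. Foxp3 differed by -2.37 ± 0.15 on the log2 scale (adjusted p = 3.6e-06), Lrrc32 by -3.02 ± 0.28, Il2ra by -1.33 ± 0.13 and Nrp1 by -1.21 ± 0.10. Gzmb was lower in TNFdARE Treg (12.7 ± 0.932 against 27.1 ± 2.06 CPM) and differed by -3.60 ± 0.45 (adjusted p = 0.0017) from the change in Tconv. Cldnd1, a claudin-like protein, rose more in Treg (0.82 ± 0.12). The Treg core list had 8 of 15 genes different (15 adjusted over the list alone; camera adjusted p = 2.1e-27, or 0.013 with an estimated correlation). The number was between 30 and 43 without any of 10 of the 12 libraries, all but Tconv TNFdARE B and WT C, and 13 in a fit of all 42 libraries. It was 43 with the sample-sheet pass, 136 with a replicate block, 185 by DESeq2 and 224 without a filter.

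In the ileum the same interaction gave 3 genes of 15916: Stab1 (-2.09 ± 0.21, adjusted p = 0.0083), Foxp3 (-2.78 ± 0.29, adjusted p = 0.0083) and Frmd5, a membrane-cytoskeleton protein (-3.84 ± 0.42, adjusted p = 0.0095). All rose more in Tconv on the log2 scale, from lower levels, while in CPM the group means of each rose more in Treg. Frmd5 stood at 7.89 ± 1.77 against 0.140 ± 0.105 CPM in Tconv and 124.6 ± 15.7 against 33.6 ± 1.78 CPM in Treg. Stab1 stood at 57.4 ± 5.86 against 3.64 ± 0.113 CPM in Tconv and 166.9 ± 17.3 against 43.6 ± 6.72 CPM in Treg. The Treg core list differed as a whole (1 gene lower of 15; 9 adjusted over the list alone; camera adjusted p = 2.3e-19, or 0.0081 with an estimated correlation). No gene passed without Treg TNFdARE B (edgeR, 630 at an unadjusted p under 0.05), nor without both experiment A Treg libraries (867 unadjusted, a choice made after the data were seen). Frmd5 was also lost without Tconv WT A or Treg TNFdARE C (adjusted p = 0.059 and 0.052). Without Treg WT B 98 passed, without Tconv TNFdARE A or C 6 or 7, without a filter 13, with a replicate block 20, in a fit of all libraries 23 and by DESeq2 77.

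Between synovial and ileal Treg, the contrast that the study's title asks about, 8 of 17132 genes differed in their genotype effect. Ttn rose more in the synovium on the log2 scale (3.23 ± 0.37, adjusted p = 0.031). It stood at 247 ± 59.3 against 3.78 ± 1.01 CPM there, and at 855 ± 213 against 124 ± 8.24 CPM in the ileum, where the rise in CPM was larger. Tap1, the peptide transporter of antigen presentation, went opposite ways (-1.33 ± 0.18, adjusted p = 0.042), at 0.60 ± 0.09 in the ileum (adjusted p = 0.011) and -0.69 ± 0.17 in the synovium, where it did not pass (adjusted p = 0.24). As a group, interferon genes had no member past the test (0 of 22; 5 lower adjusted over the list alone) and a median difference of -1.06 (camera adjusted p = 2.7e-05, or 0.11 with an estimated correlation). Effector and tissue Treg genes also had none (0 of 19; 5 higher adjusted over the list alone) and a median of 0.60 (camera adjusted p = 0.00067, or 0.28 with an estimated correlation). These calls did not outlast the removal of libraries. The number was 0 without any of the TNFdARE ileal libraries, WT ileal A or C, or TNFdARE synovial B or C (edgeR, 1057 to 1443 genes at an unadjusted p under 0.05), 2 without TNFdARE synovial A or WT ileal B, 3 without WT synovial A, and 1349 without WT synovial B. It was 0 with a replicate block, by voom, with the sample-sheet pass and without the experiment A ileal libraries, 5 without a filter, 387 by DESeq2 and 1495 in a fit of all 42 libraries.

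Site comparisons set Treg of each tissue against Treg of its draining node, genotypes weighted equally. Effector and tissue Treg genes were mostly higher in ileal than in mesenteric Treg (6 libraries against 5). Areg was 152-fold higher in the ileum than in the mesenteric node (7.25 ± 0.43, adjusted p = 3.3e-06), Gzmb 19.1-fold (4.26 ± 0.26), Ccr8 9.49-fold (3.25 ± 0.18) and Gata3, a factor of type 2 and tissue Treg, 3.08-fold (1.62 ± 0.16). Of 19 effector and tissue Treg genes 17 were higher (18 adjusted over the list alone; camera adjusted p = 1.7e-12, or 0.14 with an estimated correlation). Gpr83 was 5.59-fold lower. Immediate early and dissociation genes had 13 of 19 higher and 1 lower (14 and 1 adjusted over the list alone; camera adjusted p = 9e-07, or 0.33 with an estimated correlation), with Nr4a1, an early target of receptor signalling, 8.9-fold higher. Epithelial genes had 12 of 12 higher (12 adjusted over the list alone; camera adjusted p = 0.00061, or 0.42 with an estimated correlation). Differences between ileal and mesenteric Treg were thus not separated from tissue dissociation or RNA of other cells. Foxp3 was 1.26-fold higher (0.33 ± 0.09, adjusted p = 0.023), a call lost without mesenteric TNFdARE B or C or WT B or C (adjusted p from 0.055 to 0.12). Tnf was 1.85-fold lower (-0.89 ± 0.20, adjusted p = 0.0088), a call lost without mesenteric TNFdARE B (adjusted p = 0.055). In all 4881 of 16723 genes passed, against 2532 and 1996 without TNFdARE mesenteric B or C and 2761 with the sample-sheet pass.

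Synovial Treg differed from Treg of the joint nodes along similar lines (5 libraries against 6). Il10 was 86.8-fold higher in the synovium (6.44 ± 0.23, adjusted p = 1.1e-07), Areg 89.0-fold (6.48 ± 0.30), Gzmb 41.2-fold (5.37 ± 0.16), Klrg1 14.8-fold (3.89 ± 0.10) and Ccr1, a receptor for inflammatory chemokines, 99.9-fold (6.64 ± 0.33). Tnfaip3, which restrains NF-kB, was 18.1-fold higher (4.18 ± 0.29). Of 19 effector and tissue Treg genes 18 were higher (18 adjusted over the list alone; camera adjusted p = 3.2e-14, or 0.057 with an estimated correlation), and of 13 naive and retention genes 11 were lower and 1 higher (11 and 1 adjusted over the list alone; camera adjusted p = 0.00015, or 0.17 with an estimated correlation). Interferon genes had 15 of 22 lower (17 adjusted over the list alone; camera adjusted p = 2.4e-05, or 0.062 with an estimated correlation), with Usp18 20.2-fold lower. Immediate early and dissociation genes had 18 of 19 higher and 1 lower (18 and 1 adjusted over the list alone; camera adjusted p = 1.1e-10, or 0.14 with an estimated correlation). All 11 fibroblast and stroma genes were higher (11 adjusted over the list alone; camera adjusted p = 3.2e-14, or 0.091 with an estimated correlation). Here too, the site was not separated from tissue dissociation or RNA of other cells. Foxp3 was alike in level (-0.05 ± 0.16, adjusted p = 0.84), and the Treg core list had 5 genes higher and 5 lower of 15 (5 and 5 adjusted over the list alone; camera adjusted p = 0.84; median -0.05 and mean -0.26, camera's statistic upward). In all 6177 of 16378 genes passed, against 3347 by voom and 3639 with the sample-sheet pass.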

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

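All tests of the 3 patterns below were chosen only after the result was seen, including the 2-standard-error rule and the number of genes that decides the first test, the 2 Mb distance and the number of comparisons of the third, and a myeloid, a scaling and a paralog test that replaced earlier forms after their values were known; the splits of the samples were planned, except those that follow the experiment letters.

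Genotype effects differed between groups in tests of the difference itself. Between synovial and ileal Treg 8 genes differed, among them Ttn by 3.23 on the log2 scale, Pcmtd1 by 2.24, Tap1 by -1.33, Hpgds by 9.5, Gprasp2 by 11.7, Tmem35b by 10.68 and Zfp623 by 10.5. The last 4 named had 1 count or none in WT synovial Treg, so their fitted values depend on the prior count and are no bounds. Each of these named calls was lost without any 1 library of ileal Treg or of synovial Treg but synovial WT B (adjusted p from 0.054 to 0.23). Between ileal Treg and Tconv 3 genes differed, Stab1 by -2.09, Foxp3 by -2.78 and Frmd5 by -3.84, and none without Treg TNFdARE B (adjusted p = 0.053 for each). Between Treg and Tconv of the joint nodes 66 genes differed. Among the named ones, Foxp3 differed by -2.37, Lrrc32 by -3.02, Klrg1 by -2.74, Coro2a by -2.92, Tigit by -2.29, Il2ra by -1.33, Ctla4 by -1.57, Nrp1 by -1.21, Maf by -1.2, Il1r2 by -2.45, Arrdc4 by -2.66 and Gzmb by -3.6. Pnkd differed by 1.47, Cldnd1 by 0.82, Kif13b by 1.12, Syngr2 by 0.71 and Gbp4 by -0.5. The calls of Kif13b and Syngr2 were each lost without 10 of the 12 libraries (all but Tconv TNFdARE C and Treg WT C for Kif13b, all but Tconv WT C and Treg WT A for Syngr2), that of Gbp4 without any library but Tconv WT C, and that of Maf without Treg TNFdARE B (adjusted p from 0.051 to 0.17).

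Other splits of the same libraries were counted against the real one. Treg against Tconv called 2353 genes in the ileum, 5720 in the mesenteric node and 6351 in the joint nodes, while the highest other split called 1, 31 and 1576. Only the real split reached its number, 1 of 100, 1 of 60 and 1 of 100, so chance can be excluded over splits that disregard the experiment letters. Splits that follow the letters were not run for Treg against Tconv or for tissue against node. The same held for ileal against mesenteric Treg (4881, highest other 723, 1 of 100) and synovial against node Treg (6177, highest other 1643, 1 of 100). In the synovium 11 of 30 splits called as many genes as the real one (197, highest other 578), so chance cannot be excluded there. For the interaction in the ileum 6 of 100 splits reached the 3 genes (highest other 53), and chance cannot be excluded. For that of the joint nodes 3 of 100 reached the 66 genes (highest other 347), a share under 0.05. These splits disregard the experiment letters and also mix the genotypes within each cell type. They therefore cannot exclude chance for the interaction itself. Libraries of a letter deviated together in the joint nodes and in ileal Tconv (r from 0.2 to 0.5). Among the 32 splits that part the genotypes of every letter in each cell type, 5 reached 3 genes in the ileum (highest other 526) and 3 reached 66 in the joint nodes (highest other 1153), so among these chance cannot be excluded for either interaction. With the replicate block the interactions gave 20 and 136 genes. Splits that call several times the real count may reflect a structure of the samples, which was not tested, and those of an interaction also carry the effects of genotype and cell type. For TNFdARE against WT with 3 libraries each, 10 splits are too few for a share under 0.05. As many genes came from 2 of 10 in ileal Treg (116, highest other 163), 1 of 10 in Treg of the joint nodes (838, highest other 0), 1 of 10 in ileal Tconv (208, highest other 0) and 1 of 10 in Tconv of the joint nodes (410, highest other 3). Of these 10, 4 part every letter, and among those the real split alone reached its number in each of the 4 comparisons (highest other 1, 0, 0 and 3, in that order).

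Most Treg core genes were higher in TNFdARE Tconv at each site, although Gpr83 was lower in the ileum and the synovium rests on 1 WT library. Treg with the profile of the sorted TNFdARE Treg, at a single share in the Tconv gate, would raise every Treg core gene by that share of its difference between TNFdARE Treg and WT Tconv. In the joint nodes 10 of the 14 other genes lay more than 2 standard errors from the share of Foxp3 (2.47%, with a range of 0.972% for Il2ra to 15.8% for Izumo1r), which argues against Treg of that profile as the whole cause, while Treg of another profile stay open. In the mesenteric node 7 and in the ileum 5 of 14 did (Foxp3 shares 2.01% and 8.46%), too few at this spread to decide for the list. Of the 5 in the ileum 4 lay above Foxp3, such as Capg (48.0 ± 9.19%), and 1 below, Gpr83 (-156 ± 81.5%). Gpr83 was lower in TNFdARE ileal Tconv (8.60 against 20.9 CPM in WT), which Treg of that profile, at 28.8 CPM, would not give. For the list as a whole, Treg in the gate and a change within Tconv cannot be told apart at either site. In the synovium 3 of 14 lay that far from Foxp3 (Foxp3 share 42.5%, median of the list 47.2%). They were Capg (122 ± 9.71%), Nt5e (96.2 ± 5.48%) and Izumo1r (-28.3 ± 28.1%). Capg stood at 1097 CPM in TNFdARE Tconv against 945 CPM in TNFdARE Treg, which no share of Treg of that profile would give. For the genes nearer to Foxp3, Treg in the gate are a candidate explanation. It rests on 1 WT library, whose standard error covers counting error only. Recently activated Tconv or Treg that lost the reporter remain untested.

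Interferon-response genes were lower in TNFdARE Treg and Tconv of both node sites, although camera with an estimated correlation passed only in Tconv of the joint nodes (adjusted p = 0.034, against 0.052 in Treg there and 0.35 and 0.19 in mesenteric Treg and Tconv). A single experiment does not account for this, since the list score was lower in TNFdARE in 10 of 10 pairs of experiment and comparison, drawn from the 3 experiments. Myeloid RNA in WT is also argued against, since the interferon-response CPM lost was at least 8.1 times the summed CPM of the 15 myeloid list genes in the highest WT library (42.7 times without Cd74 and the MHC class II genes). For scaling, a factor per library moves all its genes alike, and the list median minus the median of all genes was -0.49 where it was nearest 0. Camera had already compared the list with the other genes, so this restates the flagged result and is no separate test. A lower interferon response of TNFdARE cells may remain as a hypothesis; other sources of interferon-exposed RNA and the shared origin of Treg and Tconv within an experiment were not tested.

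Genes beside Tnf on chromosome 17 were called in the same direction in 4 or more genotype comparisons. Within 2 Mb of Tnf lay 6 of 164 such genes, against 1.6 expected from the 187 of 19141 tested genes there (Fisher's exact test, two-sided p = 0.0055). They were Gm8810 (higher in 6, log2 fold changes from 4.51 to 9.44), H2-T10 (higher in 5), H2-T3, Ltb and Myo1f (higher in 4) and H2-T24 (lower in 4). A strain variant beside the targeted locus could be the source, although genes near Tnf are also rich in immune genes that inflammation may move. Reads shared between MHC class I paralogs cannot be told apart from it, since 2 of these genes were higher and 1 lower, too few to decide.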

How the results depend on the processing

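The removal of the libraries with the most genes detected and of those with the most plasma cell RNA was chosen after seeing the data; every other alternative here was planned. Of 341 named-gene results, with 314 past the test, DESeq2 kept direction and side of the threshold for 335, RLE factors for 336, the analysis without a filter for 328, the replicate block for 290 and voom for 269. On simulated data, drawn from dispersions fitted by edgeR, DESeq2 made 76 false calls among 195 in ileal Treg and 176 among 228 in synovial Treg. A call kept by DESeq2 there therefore says little. The sheet pass, where it could be estimated, kept 222 and ended 50 calls, and a fit of the 2 compared groups kept 171 and ended 41. A fit of all 42 libraries kept 112 and ended 14. Leaving out each library kept 2166 and ended a call in 330 cases. Removing the plasma-rich libraries kept 51 and ended 24, and removing those with the most genes kept 59 and ended 4. Numbers of genes past the test moved by more than 1.5 times in the following cases, and the cause was not tested. With only the 2 compared groups, ileal Treg gave 5, synovial Treg 1, ileal Tconv 636, synovial Tconv 884 and Tconv of the joint nodes 242. With the replicate block, ileal Treg gave 238, ileal Tconv 338, Treg of the joint nodes 1524, synovial Treg 0 (edgeR, 1052 unadjusted), synovial Tconv 2, synovial Treg against Tconv 71, the interactions of ileum and joint nodes 20 and 136, and that of synovial against ileal Treg 0 (1137 unadjusted). DESeq2 gave 722, 1343, 924 and 1503 in Treg of ileum, mesenteric node, synovium and joint nodes, 559, 680 and 1186 in Tconv of ileum, mesenteric node and synovium, 1601 for synovial Treg against Tconv, and 77, 185 and 387 for the interactions of ileum, joint nodes and synovial against ileal Treg. Voom gave 25, 1 and 1726 in Treg of ileum, synovium and joint nodes, 1024 and 45 in Tconv of ileum and synovium, 41 for synovial Treg against Tconv, 3347 for synovial against node Treg and 0 for synovial against ileal Treg (955 unadjusted). Without a filter, mesenteric Treg and Tconv gave 1405 and 884, synovial Treg and Tconv 140 and 231, synovial Treg against Tconv 391, and the interactions of ileum, joint nodes and synovial against ileal Treg 13, 224 and 5. With the sheet pass, the values were 1 and 506 in Treg of synovium and joint nodes, 36 in synovial Tconv, 1264 and 106 for Treg against Tconv of ileum and synovium, 43 and 0 (1369 unadjusted) for the interactions of the joint nodes and of synovial against ileal Treg, 2761 for ileal against mesenteric Treg and 3639 for synovial against node Treg. In a fit of all 42 libraries, Treg against Tconv gave 2437, 3262 and 2980 in mesenteric node, synovium and joint nodes, and the interactions of ileum, joint nodes and synovial against ileal Treg 23, 13 and 1495. Without the plasma-rich libraries both ileal interactions gave 0 (867 and 828 unadjusted). With RLE factors no number moved that far. Leaving out each library, with fewer samples by construction, gave 36 to 695 genes in ileal Treg, 221 to 663 in mesenteric Treg, 0 to 1419 in synovial Treg and 332 to 931 in Treg of the joint nodes. In Tconv of the same sites it gave 92 to 151, 131 to 380, 26 to 28 and 276 to 444. For Treg against Tconv it gave 1541 to 3090 in the ileum, 4640 to 5550 in the mesenteric node, 45 to 1287 in the synovium and 5573 to 6771 in the joint nodes. The interactions gave 0 to 98 in the ileum, 30 to 87 in the joint nodes and 0 to 1349 for synovial against ileal Treg, and tissue against node Treg gave 1996 to 6307 (ileum) and 4723 to 8459 (synovium). List results past the test numbered 197, against 34 with an estimated correlation, 180 by fry, 168 on ranks and 198 with a replicate block, and 163, 50, 35 and 13 of the 197 were lost, in that order. Signs reversed for Tnf and Foxp3 alone, and these reversed values did not pass the test. Leaving out each library took the log2 change of Tnf from -0.03 (without WT C) to 0.24 in ileal Tconv, from -0.22 (without WT A, and -0.10 without TNFdARE A) to 1.65 in synovial Treg, from -0.35 to 0.12 (without Tconv WT C) in the joint-node interaction, from -0.88 to 0.05 (without synovial WT A) in synovial against node Treg, and, for the interaction tested as Tnf in Treg genotype effect synovium vs ileum, from -0.99 to 0.88 (without synovial WT B). It took Foxp3 from -0.38 to 0.16 (without synovial WT B) in synovial against node Treg and from -0.18 (without synovial WT B) to 0.89 in the synovial against ileal interaction. With the sheet pass Tnf went to 0.14 in synovial Tconv and Foxp3 to 0.01 in synovial against node Treg, and without the libraries with the most genes Tnf went to 0.16 in the joint-node interaction. The cause was not tested. With 1 to 3 libraries per group, the fits of synovium and ileum missed most simulated 2-fold changes, so a gene that did not pass there may have changed by that much.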

Other observations

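The genes below were chosen after their values were seen, and their calls are those of the genotype comparisons. Ttn was higher in TNFdARE by 2.76, 3.66, 6.05 and 3.21 on the log2 scale in Treg of the ileum, mesenteric node, synovium and joint nodes, and by 3.65, 4.49, 7.05 and 2.92 in Tconv of the same sites. Neb, which encodes another giant muscle protein, passed in 6 of the 8 comparisons, and in the joint nodes it stood at 0.33 in Treg, where it did not pass, and 1.48 in Tconv. H2-T3 differed by 5.68 in Treg and 5.39 in Tconv of the joint nodes, Gm8810 by 6.21 and 4.51, H2-T24 by -0.61 and -0.50, H2-T10 by 0.31 and 0.79, Ltb by 0.30 and 0.24 and Myo1f by 0.63 and 0.57. Over the 8 comparisons 649 genes were called higher in a single one and 226 in 2.

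The interferon-response score of the ileum, as TNFdARE minus WT of the same experiment, was -0.13, -0.32 and 0.70 in Treg and -0.13, -0.54 and -0.02 in Tconv for experiments A, B and C. In the synovium it was -1.11 and -1.26 in Treg for A and B, and -1.95 in Tconv for A. In Treg of the joint nodes it was -0.84, -0.93 and -1.27, and in mesenteric Treg -1.42 and -0.78 for B and C.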
